A study of Arabidopsis thaliana with 12 samples.

How the data were processed

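Total RNA from light-adapted Arabidopsis thaliana plants (wild type, Columbia 0) and from such plants after 1 h of darkness was hybridised to a 1-channel expression array, with 6 samples in each group, per the labels. The deposited values are intensities on a linear scale, and the scanner, background correction and normalization used by the authors are not given in the sources used here. The values run from 0 to a common upper end just under 100, so each column was scaled and capped before deposit, as its values show. Groups and sample numbers were taken from the sample titles. The labels do not say that the samples came from separate plants or cultures, so p-values measure only the spread between these samples, which may be technical.

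Column medians ranged from 0.0644 to 0.106, beyond the tolerance of 2% set before the data were examined, so arrays were quantile normalized. Values were then raised to a floor at the 5th percentile of positive values (0.0116) and converted to log2. Fold changes are differences of mean log2 values and understate changes of dim probes. Means and SDs are those of the normalised linear values. All 3439 probes were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, contrast dark minus light), and Benjamini-Hochberg adjusted p under 0.05 was the threshold. Figures were drawn with matplotlib 3.10.9.

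The rule fixed before the data were examined averaged neighbouring sample numbers where their differences had a median SD under 0.5 of that of other pairs in both groups, and otherwise kept 6 samples against 6. It named no set of probes. Over all 3439 probes the ratio was 0.694 in the light and 0.772 in the dark, which does not meet the rule and would make 6 against 6 the analysis to report (814 probes). In all, 4 sets of probes were tried. Over the 1992 probes above 0 in every sample the ratios were 0.673 and 0.761, and over the 1014 with a mean intensity above 0.2 they were 0.519 and 0.726. Only the 276 probes with a mean above 1, with 0.376 and 0.386, met the rule. That set was chosen after the values were seen, and the numbers of changed probes under both choices were known when the decision was made. The averaged analysis (262 probes) was kept as the more cautious of these 2, because the correlation within pairs estimated by limma was 0.438. Counting the 2 samples of a pair as independent would thus overstate the number of replicates. A limma fit with the pair number as a replicate block was more cautious still, with 0 probes (smallest adjusted p = 0.0629). The averaged analysis has no such block. Averaging departs from the rule read over all probes.

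Same-numbered samples of the 2 groups were compared by their deviations from the group means. Their correlations across probes were 0.132 to 0.219 for the 6 numbers, and 0.121, 0.147 and 0.208 for the 3 averaged pairs, all over 0.1. The numbers were therefore taken to pair the samples, from the data and not from the labels. The reported fit nevertheless left the pairing out. Results with the pair number as a replicate block are given for the counts, the gene list and the named genes. The counts with and without the block had been seen together with this check. The mean correlation was 0.172 for the same number and -0.05 for numbers of other pairs (one-sided exact permutation p = 0.00139 over 720 orders, the smallest they can give). These orders shuffle single numbers freely although neighbouring numbers form pairs, so this p-value overstates the evidence.

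Gene names came from a platform annotation table and were updated by gene ID through a RefSeq gene table of assembly TAIR10.1. Of 692 probes with a single gene, 690 matched a locus. No genome build is named for the probes, so no coordinates are printed. Named genes were fixed by rule: probes with exactly 1 gene and a mean above the lower quartile, and among those that passed, the 12 with the largest rise and the 12 with the largest drop, plus the called members of each gene list with at least 5 measured genes. Gene lists were tested with camera at a preset correlation of 0.01.

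A background limit was set per sample after the data were seen, as the 95th percentile of its values among probes whose pair partner reads 0. A probe below it in all samples of a group has only a bound there. Where all samples of the brighter group were above the limit, its fold is given as "at least", from the mean log2 value of the brighter group against the higher of the limit and the probe's own value in the dimmer group. Of the 262 changed probes, 253 were above the limit in at least 4 of 6 samples of a group.

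The procedure was tested on simulated data with 200 of 3439 probes changed, in 5 runs at 3 against 3. It recovered 11.2%, 48.8%, 60.4% and 75.2% of probes changed by 1, 2, 3 and 4 on the log2 scale, and 7.21% of its calls were false, above the nominal 5%. The simulated noise was normal and independent between probes and replicates, with 1 SD per probe for both groups, no pairing and no floor. The changed probes were drawn only from those with a mean above the lower quartile and a nonzero spread, which leaves out the dimmest probes. These shares need not hold for the real data, which differ in these respects. Alternatives covered blocks, averaging, normalization, floor, filters on dim probes, the spread estimate, array weights and leaving out samples. Added after the data were seen were the 12-sample replicate block, leaving out whole pairs, subtracting a trend along the probe IDs, the background limit, and list membership of probes with several genes.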

Results

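RNA was measured in wild-type Arabidopsis thaliana of the Columbia 0 ecotype, the standard laboratory accession of this plant, with a 1-channel expression array. Of the 12 samples, 6 came from light-adapted plants and 6 from light-adapted plants moved to darkness for 1 h. The deposited table held 3439 probes on a linear intensity scale from 0 to 100. In each sample 16.3% to 22.2% of the probes stood at exactly 0, and between 3 and 8 probes stood at the upper end of the scale. A gene was named for 692 probes, several genes for 870, and 1877 probes were unnamed here. Neighbouring sample numbers (1 and 2, 3 and 4, 5 and 6) resembled each other most. On the linear scale, which bright probes dominate, their correlations across probes were 0.9945 to 0.9986 against 0.920 to 0.978 for other samples of one group. On the log2 scale all 12 samples were closest to their pair partner, but narrowly so for samples 5 and 6 of both groups, with 0.832 against at most 0.827 for other light-adapted samples and 0.932 against at most 0.929 for other dark ones. Neighbouring numbers were averaged, and every mean below rests on 3 averaged replicates per group.

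The share of probes above a background limit differed between samples. It was 38.1% and 29.8% in light-adapted samples 5 and 6, 50.5% and 47.9% in light-adapted samples 3 and 4, and 62.8% to 71.2% in the other 8 samples. Dim probes were thus less often above the limit in light-adapted samples 3 to 6 than in the rest. The limit itself was higher there. On the normalised scale it was 0.0850, 0.0934, 0.136 and 0.194 in light-adapted samples 3 to 6, against 0.0289 to 0.0501 in the rest. Counts of samples above the limit therefore compare unlike limits between the groups, and a lower count in the light does not by itself show absence there. The number of arrays limits the precision.

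The comparison asked which transcripts differed between light-adapted plants and plants after 1 h of darkness. The gene with the largest drop was AT1G02020, whose normalised intensity was 8.99 ± 5.17 (SD, n = 3) in the light and 0.0412 ± 0.0110 in the dark, a change of -7.56 on the log2 scale (SE 0.65, adjusted p = 0.00911) that became -8.22 without light-adapted samples 3 and 4. AT2G46630 was also bright in the light and fell 16.6-fold, from 8.21 ± 1.72 to 0.499 ± 0.136 (adjusted p = 0.00645). The largest rise of a named gene was that of AT4G05070, from 0.0378 ± 0.0385 to 1.47 ± 0.625, a log2 change of 5.70 (SE 0.84, adjusted p = 0.0292). It was 6.51 without light-adapted samples 1 and 2, and without samples 3 and 4 it was 5.10 and did not pass (adjusted p = 0.0614). Its size also depended on the floor, with 6.87 for a floor at the 1st percentile, which did not pass (adjusted p = 0.0621), and 4.69 at the 20th. Its probe was above the background limit in only 2 of 6 light-adapted samples, and its ID lies next to or 6 away from that of a bright probe. The probe with the ID just before it, 4360, carries several genes and rose as well. Its intensity went from 3.39 ± 0.301 to 29.1 ± 1.79 (adjusted p = 0.00387). Among genes measured above the limit in all 12 samples, AT4G13550 rose 5.54-fold, from 0.213 ± 0.0560 to 1.17 ± 0.228 (adjusted p = 0.0133). With the pair number as a replicate block in limma, AT1G02020, AT2G46630, AT4G05070 and AT4G13550 did not pass (adjusted p = 0.0726, 0.0629, 0.120 and 0.0629).

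**Figure D1:**
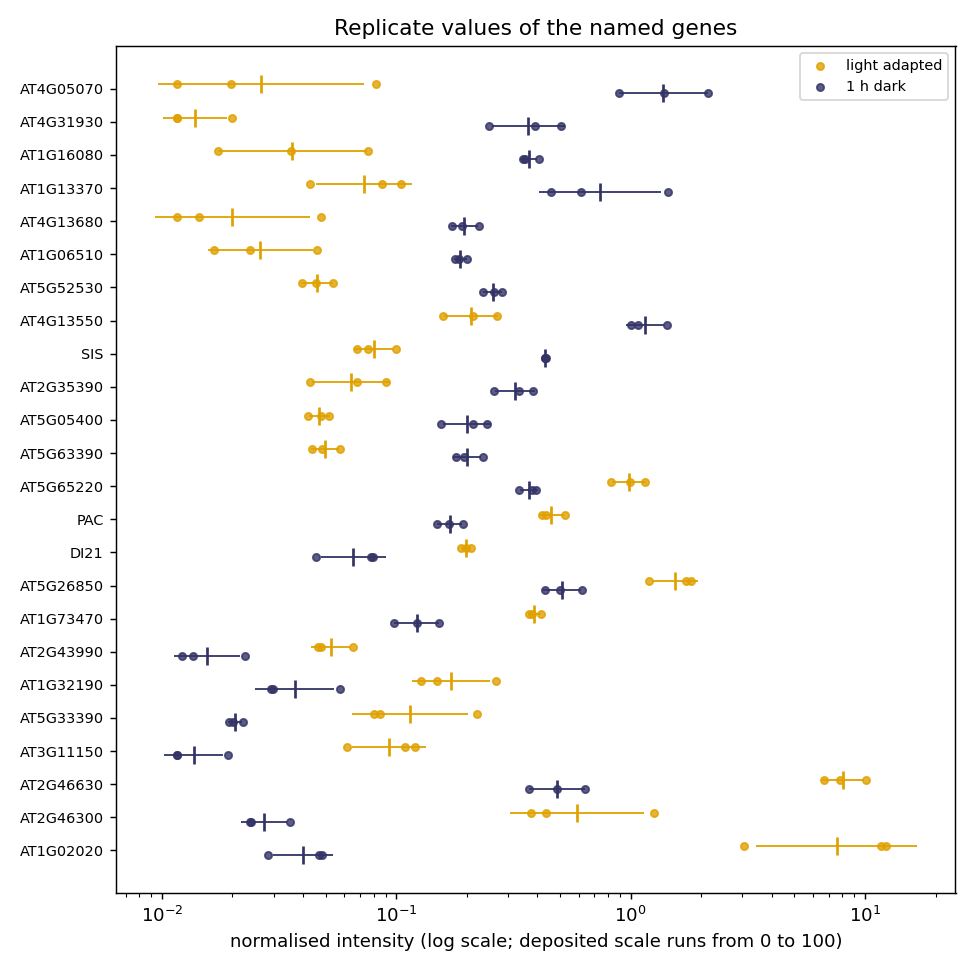
Normalised intensity (log axis) of the 24 named genes in 3 light-adapted and 3 dark averaged replicates. Points are replicates, vertical ticks the mean of log2 values and horizontal lines 1 SD of them; the groups do not overlap for any of these genes, which were chosen among the changed probes.

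Across the array, 262 of 3439 probes differed at a Benjamini-Hochberg adjusted p under 0.05 in limma. Of these 146 were higher and 116 lower in the dark, so 55.7% rose (exact Clopper-Pearson 95% interval 49.5% to 61.8%, treating probes as independent, which they are not). The split depended on the scaling: 54 rose and 101 fell without normalization, and 132 rose and 141 fell with cyclic loess. At least 4-fold changes were seen for 51 of the higher and 38 of the lower probes. Of the 262 probes, 49 carried a single gene (27 higher, 22 lower), 64 carried several and 149 were unnamed here. The groups did not overlap for 988 probes, 28.7% of all, where chance gives 10% if the 6 averaged replicates are exchangeable.

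**Figure D2:**
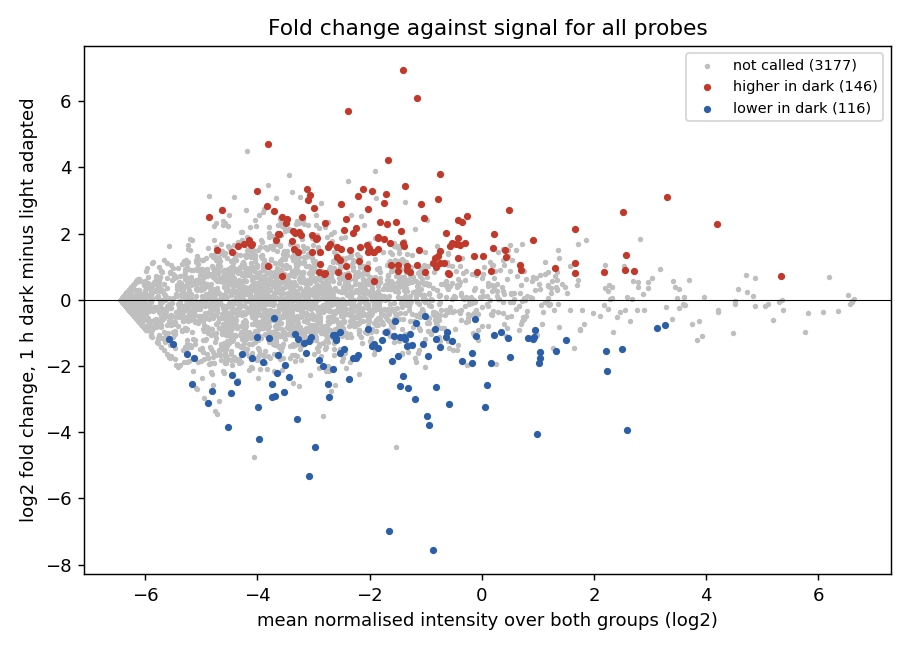
Log2 fold change, 1 h dark minus light adapted, against the mean log2 normalised intensity of both groups for 3439 probes. The 146 higher (red) and 116 lower (blue) probes spread over nearly the whole intensity range, and the wedge at the left is set by the floor applied to dim values.

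These calls depended on how the replicates were modelled. With the pair number as a replicate block no probe passed (0 in limma, 797 at an unadjusted p under 0.05, smallest adjusted p = 0.0629). Without averaging, 6 samples against 6 gave 814 probes. Leaving out a whole pair of dark samples left 13 probes without samples 1 and 2, 84 without samples 3 and 4 and 64 without samples 5 and 6. Leaving out the light-adapted pairs in the same order gave 212, 198 and 234 probes. Of the 262 probes 143, 142 and 157 stayed called there, and of the 24 named genes 18, 13 and 16. Of the 24 named genes, 1, AT2G46630, stayed called without dark samples 1 and 2, and 9 did without each of the other dark pairs. Without normalization 114 of the 262 probes and 14 of the 24 named genes stayed called. The 10 genes lost there, with adjusted p of 0.0529 to 0.125, were AT4G05070, AT1G16080, AT1G13370, AT4G13680, AT2G35390, AT5G05400, AT5G63390, AT5G33390, AT1G32190 and AT5G26850.

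Of the 12 named genes that rose most, several belong to known gene families. AT1G13370, a histone H3 family gene, rose 10.1-fold from 0.0780 ± 0.0318 to 0.836 ± 0.530 (adjusted p = 0.0421). AT2G35390, which encodes a phosphoribosyl pyrophosphate synthetase of nucleotide synthesis, rose 5.02-fold from 0.0672 ± 0.0240 to 0.326 ± 0.0620 (adjusted p = 0.0262). SIS, named for its induction by salt, rose 5.40-fold from 0.0811 ± 0.0163 to 0.433 ± 0.00182 (adjusted p = 0.00645). Calls of AT1G13370 without light-adapted sample 2 (adjusted p = 0.0529) and of AT2G35390 without light-adapted sample 1 or 6 (up to 0.0544) were lost. AT5G05400, a gene of the leucine-rich repeat disease resistance family, rose 4.27-fold (adjusted p = 0.0124, but 0.108 without normalization). In the light AT1G13370 and SIS were above the background limit in only 3 of 6 samples and AT2G35390 and AT5G05400 in 2 of 6, so these 4 folds were taken against levels near background. AT4G31930, a mitochondrial glycoprotein family gene, was above background in none of the 6 light-adapted samples and in all 6 dark ones. It was at least 4.72-fold higher in the dark (adjusted p = 0.00892), with a fitted log2 change that moved from 3.09 to 6.67 with the floor, and its ID too lies next to or 6 away from that of a bright probe.

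Light-adapted levels of AT4G13680 and AT1G06510 were likewise below the limit in every sample, and these genes were at least 2.51-fold and at least 2.42-fold higher in the dark (adjusted p = 0.0450 and 0.0258). Both calls were lost with the floor at the 1st percentile (adjusted p = 0.0942 and 0.0631), as was that of AT1G16080 (0.0825), and the fitted log2 changes of the first 2 were 2.0 and 2.09 at the 20th percentile. The other rising genes were AT1G16080 (10.2-fold), AT5G52530 (5.63-fold) and AT5G63390 (4.06-fold), with adjusted p of 0.0383, 0.00645 and 0.00899. The value of AT5G52530 rested on light-adapted samples 5 and 6: its log2 change of 2.49 became 3.15 without sample 5 (adjusted p = 0.0571) and 1.84 without sample 6 (adjusted p = 0.170), and neither passed. With neighbouring numbers as random blocks it did not pass either (adjusted p = 0.0851). AT1G16080 was lost without light-adapted sample 1 or 5 (adjusted p up to 0.0634), and AT4G13680 without light-adapted sample 5 or dark sample 5 (up to 0.123). The fitted log2 change of AT4G13680 went from 3.28 to 3.92 without light-adapted samples 5 and 6. AT1G16080, AT5G52530 and AT5G63390 were each above the limit in 2 or 3 of 6 light-adapted samples and in all 6 dark samples.

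Among the genes that fell, PAC, a gene needed for chloroplast development, dropped 2.71-fold from 0.461 ± 0.0584 to 0.170 ± 0.0213 (adjusted p = 0.0128, but 0.0747 after subtracting a trend along the probe IDs). AT5G65220, which encodes protein L29 of the plastid ribosome, dropped 2.67-fold from 0.990 ± 0.161 to 0.369 ± 0.0309 (adjusted p = 0.0148). DI21, named as a drought-induced gene, fell 3.02-fold from 0.198 ± 0.010 to 0.0677 ± 0.0193 (adjusted p = 0.0332), a call lost without dark sample 2 or 4 (up to 0.0755). AT5G26850 fell 3.03-fold (adjusted p = 0.0278, but 0.0618 without normalization) and AT1G73470 fell 3.16-fold (adjusted p = 0.0151), both above background in all 12 samples.

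AT2G46300 fell 21.8-fold from 0.692 ± 0.495 to 0.0276 ± 0.00659 (adjusted p = 0.0190), with 3 of 6 dark samples above the limit. Its size depended on the floor, with a log2 change of -5.62 at the 1st percentile and -3.50 at the 20th. AT1G02020 was above the limit in 3 of 6 dark samples as well. AT1G32190 fell 4.66-fold and lay closest to the threshold (adjusted p = 0.0498), which it missed with the floor at the 1st percentile (0.0530) and with the trended, robust spread estimate (0.0528). Dark levels of AT3G11150, AT5G33390 and AT2G43990 were below the limit in all 6 samples (adjusted p = 0.0216, 0.0438 and 0.0383). In the light AT3G11150 and AT5G33390 were above the limit in only 3 of 6 samples and AT2G43990 in 2 of 6, so the sizes of these drops were not determined. With the floor at the 20th percentile the last 3 had log2 changes of -1.11, -1.41 and -0.42 and did not pass (adjusted p = 0.0965, 0.153 and 0.0708), against -2.77, -2.48 and -1.75. At the 1st percentile AT3G11150 and AT5G33390 passed with -4.42 and -3.29, and AT2G43990 did not (adjusted p = 0.0598), nor under median scaling (0.0691). Single samples mattered as well, since AT2G46300 was lost without dark sample 5 (adjusted p = 0.0676), AT3G11150 without light-adapted sample 1 or dark sample 6 (up to 0.0620) and AT2G43990 without light-adapted sample 2 or 3 or dark sample 6 (up to 0.0999). AT5G33390 was lost without light-adapted sample 3 or 6 or dark sample 1, 3 or 5 (up to 0.0946), and AT1G32190 in 9 of 12 such fits (up to 0.0795), all but those without light-adapted sample 3 or 5 or dark sample 3. With the replicate block none of the 24 named genes passed, with adjusted p up to 0.155 for AT1G32190.

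Genes of photosynthesis and plastid metabolism were sparsely covered by probes with a single name. Of 377 genes in 22 lists fixed beforehand, 19 were measured, and 13 lists had no measured member. Only the list of plastid ribosomal proteins reached 5 members. Of its 6 measured genes 1 fell, AT5G65220, none rose, and the count adjusted over the list alone was also 1. Its median log2 change was 0.19 and its mean 0.16, and camera found no shift against other probes (p = 0.935, with an estimated correlation p = 0.963, and p = 0.642 with the replicate block). This says little about the list, since RPS6 was above the background limit in none of 12 samples, RPS10 in 1 and RPL34 in 4. RPL17 of this list had a log2 change of 1.62 that did not pass (adjusted p = 0.156), and RPL5 one of 0.38 (adjusted p = 0.326).

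No other list member passed over all probes, and over the 19 genes alone 1 passed. Phosphoribulokinase (PRK), the Calvin cycle enzyme that makes the acceptor of carbon dioxide, had 4.61 ± 0.486 in the light and 2.52 ± 0.534 in the dark (adjusted p = 0.0676) and passed only when adjusted over the list alone, which had 2 measured genes. The other member, SBPASE, stood at the floor in every replicate. The antenna protein gene LHCB1.5 was bright, with 45.8 ± 3.24 in the light and 37.1 ± 1.21 in the dark (adjusted p = 0.105), and passed only adjusted over the list alone, of which it was the single measured gene. Photosystem II subunit PSBW had 21.0 ± 6.91 and 34.6 ± 6.37 (adjusted p = 0.20). PSBY and PSB27 of photosystem II, PSAN of photosystem I, CHLM and CHLP of tetrapyrrole synthesis, PRXIIE and NTRC among redox proteins, the plastid protease SPPA and FATB of fatty acid synthesis did not pass. PRXIIE and SPPA were above the background limit in no sample, and NTRC in 1 of 6 light-adapted samples, so their values say little. FATB had the largest value among these, a log2 change of 2.07 (adjusted p = 0.221). It was above the limit in 2 of 6 light-adapted samples, so this change was taken against a level near background. Dark-inducible, clock, starch, photorespiration, wounding, other-cell-type marker and reference genes were among the lists with no measured member.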

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

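Leaving out whole pairs, the 12-sample replicate block, the position correction and the background limit were chosen after the data were seen. The 262 changed probes became 0 with the pair number as a replicate block (797 at an unadjusted p under 0.05), a fit with fewer residual degrees of freedom. They became 584 with neighbouring numbers as random blocks, 853 with numbers 1 to 3 against 4 to 6 as a block, 814 without averaging and 781 with the sample number as a replicate block over 12 samples, fits that enter all 12 samples. Without normalization there were 155, of which 34.8% rose and 114 were among the 262. The median log2 change of all probes was then -0.0779, against 0 in the reported fit, so the whole set of values was shifted downward. With median scaling 53.4% rose, and with cyclic loess 48.4%. The cause of these differences was not tested. Over settings that left out samples the count ranged from 13 to 274, the share that rose from 30.8% to 60.1% and the median of plastid ribosomal proteins from -0.0545 to 0.510 (log2). The lowest values, including the reversed median, came without dark samples 1 and 2. The count was 84 without dark samples 3 and 4 and 64 without 5 and 6. Without the light-adapted pairs it was 212, 198 and 234, so there the same loss of replicates came without such a drop. Leaving out a pair changes the spread as well as the number of replicates, and this comparison cannot part them. The averaged light-adapted replicates correlated less with each other (0.858 to 0.897) than the dark ones (0.925 to 0.952). The fit takes 1 spread per probe for both groups, so its p-values assume equal spread. Whether unequal spread gives the drop was not tested. Leaving out single samples gave 209 to 274. Other settings gave counts within 1.5 times of 262. The camera list test passed under none of 34 settings (p from 0.568), also not with the replicate block. The only called member of that list, AT5G65220, lost its call with the block in limma (adjusted p = 0.0994). Of 786 estimates of the 24 named genes under alternatives, 567 differed from the reported ones, all with the same sign; a balanced block cannot move an estimate. The threshold was missed by 47 estimates under other settings and 109 with samples left out. Apart from the block, named genes were lost without normalization (10), with the floor at the 1st (6) or 20th percentile (3), and 1 each with median scaling, random blocks, the trended spread estimate and the position correction. Leaving out a single sample ended the call of 11 of the 24 at least once. Dim signal limits the folds, since up to 22.2% of a sample's probes stood at 0.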

Other observations

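Outside the 24 genes of the naming rule, 24 further single-gene probes above the lower quartile passed, and those given here were chosen after their values were seen. CML41, which encodes a calmodulin-like protein, rose 3.55-fold (adjusted p = 0.0128), while CML30, of the same family, fell 2.2-fold (adjusted p = 0.0196). IAA31, a member of the Aux/IAA family of auxin response regulators, fell 1.97-fold to 0.902 ± 0.0359 (SD, n = 3, adjusted p = 0.0143). AT1G01250, an ERF family transcription factor gene, fell 2.17-fold (adjusted p = 0.0279). CRR21, which is needed for RNA editing in plastids, rose 1.65-fold (adjusted p = 0.0315). AT3G06570 was the brightest of these genes and fell 1.79-fold to 6.51 ± 0.431 (adjusted p = 0.0149). AT2G19280 rose 3.93-fold to 2.35 ± 0.550 (adjusted p = 0.0279). CML41 was above the background limit in 5 of 6 light-adapted samples and CRR21 in 2 of 6, and the others in all 12. The probe of CML41 lies near a bright probe by ID. With the replicate block none of these genes passed. All but IAA31 lost the call without normalization, and CML30, IAA31, AT1G01250, CRR21 and AT3G06570 lost it when the position trend was subtracted. AT3G06570 also lost it with median scaling. CRR21 missed the threshold under 21 of 33 alternatives and AT1G01250 under 11. AT2G19280, AT3G06570 and CML30 missed it under 7 each, IAA31 under 6 and CML41 under 5. Each of these genes lost the call in 2 to 5 fits that left out a whole pair. No gene changed sign.

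Some of the largest changes belonged to probes without a single gene name. The probe with ID 1 fell from 3.68 ± 1.09 to 0.0293 ± 0.00897 (adjusted p = 0.00636), and that with ID 3491 rose from 0.0558 ± 0.0159 to 3.79 ± 0.887 (adjusted p = 0.00636); both lost the call only with the replicate block, but the log2 change of the first went from -6.97 to -3.72 when the position trend was subtracted. Counting probes with a single gene together with those whose several genes all belong to 1 list, 24 probes stood in the lists. Of these, 1 was higher, a probe with several genes of tetrapyrrole synthesis. The 1 that was lower was the probe of AT5G65220 already given (plastid ribosomal proteins).

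The tests of shared spots, of fixed spot layout and of an excess at IDs 6 apart were chosen only after the results were seen; the tests of splits, of position, of the subtracted trend and of bright neighbours were set down before their own values were seen. All 3 patterns below had by then been noticed in the same data, and the trend subtraction was added because of the second. Of the 10 splits of the 6 averaged replicates, 1, the real one, gave as many changed probes (262), and the highest of the others gave 2. The 10 splits are too few for a share under 0.05. They treat the replicates as exchangeable although the numbers pair them, and every other split mixes dark and light, so real differences would widen its spread.

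The first pattern was that same-numbered dark and light samples deviated together, by a mean correlation of 0.172 across probes. A candidate explanation is that both samples of a number were read from the same physical spots, for example by reusing a filter with duplicate spots. The difference between odd and even samples of a pair correlated by 0.204 between dark and light of the same pair number, against 0.0774 across pair numbers. That difference is built from the same deviations, which gave a mean correlation of only 0.0150 for the other number of the same pair. A positive value was thus largely given in advance and does not tell shared spots from other sources. A fixed layout difference on all filters may account for the part shared across numbers and stays open. No biological explanation was tested, and samples of a number handled at the same time also remain possible.

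The second pattern was that fold changes of probes 6 IDs apart were correlated. Of the ID distances 1 to 24, only 6, 12, 18 and 24 gave r above 0.05 (0.0983 at 6, permutation p = 0.0001, the smallest 10000 permutations can give), and 6 larger multiples of 6 gave 0.0252 to 0.0640. Position on the array may contribute. Differences between replicates of one group correlated by a mean of 0.0950 at distance 6, which met the value set beforehand. This mean was 0.142 in the light and 0.0480 in the dark, so the light-adapted samples carried most of it. The mean of 0.0950 was not specific, because the replicate differences correlated at every distance tested near 6. At 6 their correlation exceeded that at distances 5 and 7 by only 0.0228, against 0.102 for the fold changes. After subtracting the trend 266 probes passed, and 67.2% of the 262 stayed called (176, against 182 under median scaling). Of the 262, 261 kept their sign, and 23 of the 24 named genes stayed called. The share kept lay below the value set beforehand for setting the trend aside and above that for blaming it. The test was thus undecided, and how many calls the trend made stays open.

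The third pattern was that several of the largest fold changes lay 1 or 6 IDs from a probe brighter than 10. If signal spilled from bright spots, calls should be more frequent there, but 10 of 131 such probes passed against 247 of 3260 others. The odds ratio was 1.01 (95% interval 0.465 to 1.95, Fisher's exact test p = 1), which argues against spill between such IDs as a source of the calls as a set. The array layout was not used, so whether these probes lie side by side is not known. The test took probes as independent and counted calls of any size and either direction, so it did not address the largest changes by themselves. The odds ratio leaves open spill at single probes, such as that of AT4G31930 or that of AT4G05070, whose neighbour by ID rose as well. It also leaves open a response to darkness.

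Signal level also followed the probe IDs. Among 261 probes with an ID divisible by 6 the mean log2 intensity was -5.99, near the floor, and 6.90% were above the background limit in at least 4 of 6 samples of a group (exact 95% interval 4.14% to 10.7%). In the other ID classes the means were -2.74 to -3.54 and the shares 66.3% to 77.9%. A gene was listed for 45.6% of the probes with an ID divisible by 6, and 2 of these 261 probes passed the test. In the classes with remainders 2 to 5, 47 of 654, 49 of 658, 43 of 653 and 44 of 620 passed. The class with remainder 1 had the highest share, with 77 of 593.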
